A study of Caenorhabditis elegans with 2 samples.

How the data were processed

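ChIP-seq peak lists of HLH-11 with a C-terminal GFP-FLAG tag were analysed from 2 biological replicates of whole L4 larvae. Per the labels, an antibody against GFP was used, chromatin was sonicated to a size range of 200 to 800 bp, and positions refer to build ce11. Per the file headers and accompanying notes, peaks were derived from the alignments and 1 further file, which the labels' control entry points to as a control. The control itself was not analysed here. The aligner, the peak caller and their settings are not given in the sources used here.

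4 lists were used: one per replicate, one from the pooled replicates, and one thresholded list, which the authors made by the irreproducible discovery rate (IDR), a method that keeps peaks ranked alike in both replicates. The first 3 hold 30000 peaks each, strong peaks and background together, and are inputs to that method. The thresholded list holds 7863 peaks. All 7863 were found unchanged in the pooled list and are its strongest 7863, so the list equals a minimum signal on the pooled replicates. Per the deposited files, each peak has a signal value, a height given by the authors' caller, which was used only to rank peaks and to describe them within a list. The authors' −log10 q values reach a ceiling shared by 5993 of the thresholded peaks and were not used for ranking. The summit offset gave each summit. Of the thresholded peaks, 4537 (57.7%) have a width of 424 bp, so widths were not compared. Some peaks share an interval, and 7752 intervals are distinct. In 1 thresholded peak the summit offset reached past the peak end. The lists hold no read counts, so the depth of each replicate is unknown and no interval for read counting can be given. Intervals on shares are exact binomial intervals at 95% and cover the counting of peaks or genes.

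Genes and sequence were taken from the WBcel235 reference, whose chromosomes match ce11 in length. Promoters ran from 1000 bp upstream to 500 bp downstream of any annotated start of a protein-coding transcript. The other classes were assigned in the order coding exon, 5' UTR, 3' UTR, intron, non-coding gene and intergenic. A gene counted as bound when a thresholded summit lay in that window, so that 1 peak could count for both genes of a divergent promoter. Shares of classes were compared with 10000 random placements on the same chromosomes, and chromosome counts with exact binomial tests. E-boxes and all hexamers on both strands were counted within 50 bp of the summit and in windows of the same total width centred 300 bp to either side, and compared per peak by an exact sign test. The flanking windows come in 2 pieces and offer fewer start positions. With equal numbers of start positions, a setting chosen after seeing the data, the CAGCTG ratio was 2.52, and 937 hexamers were higher and 595 lower. Gene lists were compared by Fisher's exact test, and Benjamini-Hochberg adjustment was applied over chromosomes, classes, E-boxes, hexamers or lists. All tests are two-sided. The peaks of 1 list come from the same 2 libraries, so p-values across peaks or genes measure the pattern over the genome and not variation between worm cultures.

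The 31 gene lists, the main test of each result, the rule for named genes and the alternatives listed in this paragraph were fixed before the data were examined. The rule names hlh-11, unc-119 and atgl-1, the nearest protein-coding gene of the 20 strongest peaks, up to 4 bound members of each list by peak signal, the 10 hexamers with the smallest p and all E-box hexamers. List members that are not protein-coding, such as the microRNA genes of the heterochronic list, or whose symbol had no match, were left out. Alternatives were: the stronger peaks only, overlapping peaks merged, each replicate's own strongest 7863 peaks in place of the thresholded list, peaks within 25000 bp of hlh-11 and unc-119 left out, other promoter and motif windows, other match distances and other backgrounds. The 2 background sets were pooled summits more than 500 bp from any thresholded summit (20549 summits) and the genes with any of the strongest 20000 pooled summits. Chosen after seeing the data were the omission of peaks at tRNA, snoRNA and snRNA genes, equal numbers of start positions, every alternative for the hexamer counts, the shuffled windows and the pooled summits as backgrounds for hexamers other than CAGCTG, and the tests of non-coding gene classes, of sequences at the peaks of gene lists, of CAGCTG strength against other E-boxes and of X below the threshold.

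The measurements were tested on simulated data, after first values from the real lists had been seen. Among 5000 simulated peaks, a promoter share of 58.8% and an X to autosome ratio of 1.50 were recovered as 58.8% and 1.49. CAGCTG was planted so that 22.8% of simulated summit windows held it, and it ranked 1 among all hexamers. Real summits had it in 4.32% of cases, so recovery of so rare a sequence was not tested. A list of genes bound with an odds ratio of 6.00 over 19973 genes was recovered at 5.45. That list was made larger after a small one had given an estimate further below its true value, and the null rate replaced a single draw in which an unaffected list had passed. With no list enriched, 2.50% of 1000 list tests had a p under 0.05. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.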

Results

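The genomic binding of HLH-11 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in Caenorhabditis elegans. HLH-11 is a basic helix-loop-helix (bHLH) transcription factor, the worm relative of mammalian AP-4, and bHLH factors bind short E-box sequences of the form CANNTG. The worms were of strain OP396, which carries a transgene for HLH-11 with GFP and FLAG at its C-terminus, and the protein was recovered through GFP. Whole L4 larvae of mixed sex were collected at 53 hours, after synchronisation by hatching into starvation. The series holds 1 group of 2 biological replicates, so no conditions were compared. The question addressed is where on the genome the tagged protein was found. Each replicate has a list of 30000 ranked peaks and the pooled replicates another 30000. A thresholded list of 7863 peaks, the strongest of the pooled list, carries the results. Read depth is unknown because the lists hold no read counts, and positions are on build ce11.

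The HLH-11 ChIP-seq gave 7863 peaks, which covered 2804 kb in 7476 separate regions, or 2.80% of the nuclear genome. The peak signal, a height given by the authors, had a median of 181 and reached 2943. The highest signal stood on chromosome III at 4281810 to 4282672, in intergenic sequence with its summit 1957 bp upstream of sup-26, which encodes an RNA-binding protein. The next were an intergenic peak on X at 16929427 to 16931675 (signal 2864) and a promoter peak of W03C9.5 on II at 11967426 to 11967980 (2856). The nearest start to the peak on X was that of C30E1.4, at 5821 bp. The fourth, on III at 3867308 to 3867809, lay 286 bp upstream of the ribosomal protein gene rpl-3, with a signal of 2804. Further promoter peaks among the strongest 20 were nearest to tasp-1, tos-1, ztf-7, the Pumilio-family gene puf-9, serp-1.1, tag-340, the Hsp70-type chaperone gene F44E5.4, the cell-cycle regulator lin-9 and epn-1. Intronic peaks were nearest to pqn-41 (2 peaks), ppfr-1 (6596 bp from its start), the autophagy gene epg-9 and Y111B2A.12. The remaining 2 were nearest to the calmodulin gene cmd-1 and to bcat-1, an amino acid transaminase gene. Their summits lay 4774 bp from the cmd-1 start, inside a non-coding gene, and 5018 bp from the bcat-1 start. In all, 11 of these 20 summits lay in promoters, 5 in introns and 3 in intergenic sequence, and 8 of the 20 were on chromosome III. Each of the 20 ranked among the strongest 22 peaks of both replicates.

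The transgene's own components were not sites of strong signal. No thresholded peak lay within 2000 bp of hlh-11 (III, 9619711 to 9626529). The unc-119 gene, a neuronal gene whose wild-type copy marks such transgenes, held 1 weak intronic peak at III 10905073 to 10905496, with a signal of 111 and rank 6477. Within 25000 bp of the middle of the gene, hlh-11 had 2 thresholded peaks and unc-119 had 1, against a median of 3.5 in windows of the same size along that chromosome. By contrast, atgl-1 (III, 6415772 to 6419459, minus strand), which encodes the main lipase of stored fat, had 3 peaks upstream. The strongest, at III 6420963 to 6421517, had a signal of 1419 and rank 63, and ranked 54 and 70 in replicates 1 and 2. Its summit was 1773 bp upstream of the atgl-1 start, inside the 3' UTR of the neighbouring gene C05D11.8. A peak at III 6420294 to 6420465 (signal 215) had CAGCTG within 50 bp of its summit, 931 bp upstream, and one at III 6419652 to 6419813 (signal 189) lay 246 bp upstream without that sequence. The tallest of these 3 peaks thus lies outside the 1000 bp promoter window used for gene counts.

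Almost all strong peaks were found in both replicates, and the share for weak peaks depended on how much of each replicate's list was searched. Of the 7863 peaks, 6865 (87.3%, 95% exact binomial interval 86.6 to 88.0) had a summit within 100 bp among the strongest 7863 peaks of replicate 1. The share was 89.4% (88.7 to 90.1) for replicate 2, 78.6% (77.7 to 79.5) for both and 1.83% for neither. Among the strongest 1965 peaks 99.1% were found in both, but among the weakest 1965 only 30.3% were (28.3 to 32.4). Weak peaks fall near the end of lists of that length, and 97.8% and 97.6% of the 7863 peaks had a partner in the whole lists of replicates 1 and 2, so most of the gap is set by the length searched. Across the 7508 peaks matched in both whole lists, peak signals correlated with a Spearman rho of 0.850 (permutation p = 1e-05, the smallest that 100000 resamples can give). Peaks are not independent replicates, so this p describes agreement across the genome of these 2 libraries. The 7863 peaks are the strongest of the list from the pooled replicates, to which both replicates contributed. Part of the support is therefore built in by that selection, and its effect on the support and on the rho was not tested. Compared directly, 79.1% of the strongest 7863 peaks of each replicate had a partner among the strongest 7863 of the other. The support in both replicates was 41.6% when only the strongest 3931 peaks of each replicate were searched.

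Peaks were densest on the X chromosome. X held 1869 peaks, 105 per Mb, against 72.6 per Mb on the autosomes, a ratio of 1.45 (95% interval 1.38 to 1.53). X carried 23.8% of peaks on 17.7% of the genome (exact binomial test, two-sided, adjusted p = 1.69e-41 over 6 chromosomes). Chromosomes II and III had 84.0 and 83.1 peaks per Mb, with adjusted p of 0.0126 and 0.0416. Chromosomes IV and V were sparse at 61.9 and 64.5 per Mb (adjusted exact p = 3.38e-18 and 3.17e-16), and chromosome I did not pass the test (75.1 per Mb, adjusted p = 0.118). The central 33.3% of each chromosome, where conserved and widely expressed genes concentrate, held 41.7% of the peaks (exact binomial p = 4.4e-54). Pooled peaks below the threshold were distributed differently: the X to autosome ratio was 1.15 and 31.5% lay in the chromosome centres. Neighbouring peaks are not independent, which makes these p-values too small.

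**Figure D1:**
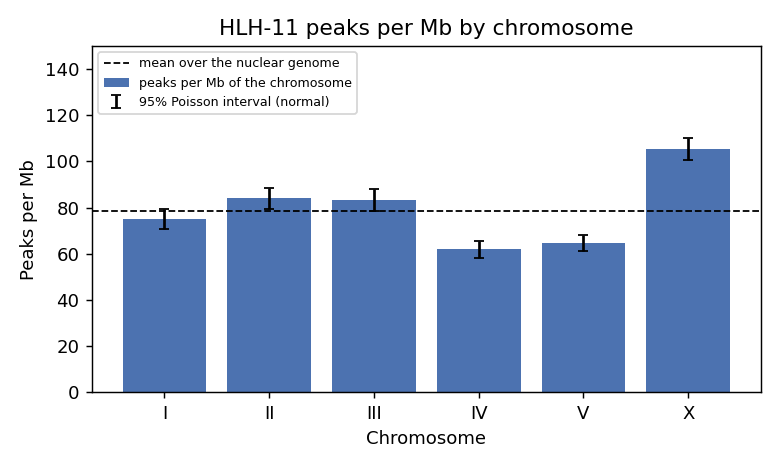
Thresholded HLH-11 peaks per Mb (vertical axis) on each nuclear chromosome (horizontal axis); error bars are 95% Poisson intervals in the normal approximation and the dashed line is the genome mean. X stands highest at 105 peaks per Mb, and IV and V lowest at 61.9 and 64.5.

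HLH-11 peaks favoured promoters and avoided coding sequence. Summits in promoters, taken as 1000 bp upstream to 500 bp downstream of a protein-coding start, numbered 4171, or 53.0% against 31.4% of random positions on the same chromosomes (1.69-fold, permutation p = 1e-04, the smallest that 10000 placements can give). Coding exons outside promoters held 2.00% of summits against 16.5% at random, introns 15.7% against 24.4%, and 3' UTRs 0.801% against 2.33%. Intergenic sequence was slightly over-represented, at 24.7% against 21.9%. All 4 differences had the same smallest p and an adjusted p of 0.00014 over 7 classes. Non-coding genes (3.48% against 3.32%, adjusted permutation p = 0.431) and 5' UTRs (0.229% against 0.148%, adjusted permutation p = 0.085) did not pass the test. The median summit lay 746 bp from the nearest protein-coding start, 71.6% of summits were on the upstream side, and 4.73% were more than 5000 bp away.

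**Figure D2:**
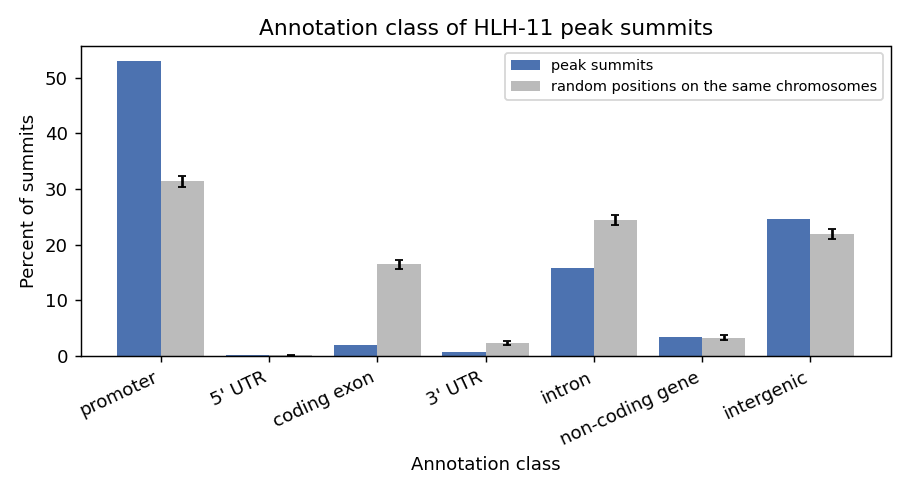
Percent of peak summits (vertical axis) in each annotation class (horizontal axis), beside the mean of 10000 random placements on the same chromosomes, whose error bars span 95% of placements. Promoters hold 53.0% of summits against 31.4% at random, and coding exons 2.00% against 16.5%.

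E-boxes were more frequent at summits than beside them, but a small share of peaks had any given one. CAGCTG, the E-box known for the AP-4 family, lay within 50 bp of 340 summits (4.32%) and in flanking windows of the same width of 131 peaks (1.67%), a ratio of 2.60. The sign test, exact and two-sided, gave an adjusted p of 2.3e-23 over the 10 E-box hexamers, with 326 peaks having it at the centre alone and 117 in the flanks alone. CACGTG, the E-box of the Myc and Max family, was more enriched, at 5.75% against 1.76% (3.28-fold, adjusted exact p = 2.23e-41), and CACATG was found at 8.09% against 3.43% (2.36-fold, adjusted p = 3.25e-36). CACCTG, CAAGTG, CAACTG and CAGATG were higher at summits by 1.66, 1.66, 1.62 and 1.42 times, with adjusted p of 4.88e-06 or less. Shuffling each summit window with its dinucleotide counts kept ended the call for CACCTG (1.16 times the shuffled share, adjusted exact p = 0.109 over 24 named hexamers) and CAGATG (1.04 times, adjusted p = 0.633). Both were slightly less frequent at thresholded summits than at pooled summits below the threshold (ratios 0.958 and 0.926, adjusted exact p = 0.519 and 0.197). CAAATG, CAATTG and CATATG did not pass the test (ratios 1.01, 0.951 and 1.02). Against pooled summits below the threshold, where 3.44% had CAGCTG, the ratio for that hexamer was 1.26 (Fisher's exact p = 0.000484). In the same comparison the ratio was 1.83 for CACGTG and 1.77 for CACATG, and over shuffled windows it was 2.56 for CAGCTG, 2.81 for CACGTG and 1.46 for CACATG.

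CAGCTG was most frequent at the strongest peaks. It lay within 50 bp of the summit in 7.18% of the strongest 1965 peaks and in 3.16% of the weakest 1965 (odds ratio 2.37, Fisher's exact test, two-sided, p = 1.28e-08). Most of the difference came from the top of the list: the strongest 786 peaks had it in 11.1% of cases, the next 786 in 5.34%, and each later group of about that size in 2.67% to 4.45%. Of the 20 strongest peaks, 4 had CAGCTG within 50 bp, those nearest W03C9.5, tag-340, F44E5.4 and lin-9.

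**Figure D3:**
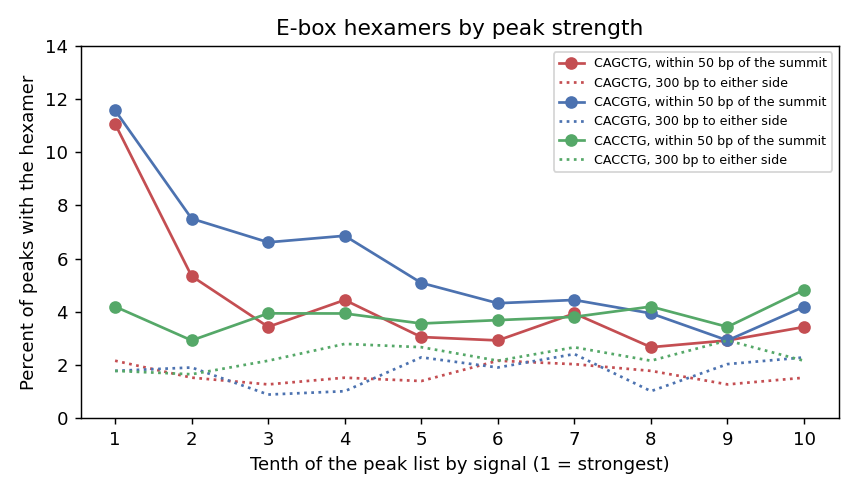
Percent of peaks (vertical axis) with CAGCTG, CACGTG or CACCTG within 50 bp of the summit (solid lines) or in windows 300 bp to either side (dotted lines), in 10 groups of the list from strongest to weakest (horizontal axis). CAGCTG falls from 11.1% in the strongest group to 5.34% in the next and CACGTG from 11.6% to 7.51%.

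Other sequences marked the summits more widely than the E-boxes. Over all hexamers, 1020 were more frequent at summits than in the flanks and 527 less frequent (adjusted p under 0.05). Much of this went with base composition: against shuffled windows, a comparison chosen after seeing the data, 329 of the 1020 were still more frequent and 209 were less frequent, and 299 of the 527 were still less frequent and 65 more. The GC content within 50 bp of summits was 44.1%, against 35.1% in the flanks and 35.4% over the genome. The 10 hexamers with the smallest p were 8 A/T-only sequences that were rarer at summits and a GA repeat in its 2 phases. AAAATT was the leading one, in 15.6% of summit windows and 41.5% of flanks, and AAAAAT (22.7% and 47.5%), TTAAAA, AAATTA, AAATTT, TAAAAA, TTTAAA and AAAATA followed the same direction. With base composition kept, TTAAAA and TTTAAA alone of the 8 were still rarer (0.796 and 0.728 times the shuffled share, adjusted exact p = 2.13e-06 and 4.59e-06). AAAATT was at 15.4% of shuffled windows (adjusted exact p = 0.739), AAATTA and AAATTT did not pass the test (adjusted p = 0.202 and 0.209), and AAAAAT, TAAAAA and AAAATA were more frequent than after shuffling by 1.3, 1.15 and 1.46 times. GAGAGA was found at 24.0% of summits and 5.70% of flanks (4.21-fold), and AGAGAG at 20.7% and 4.60% (4.50-fold). Over shuffled windows they were 2.12 and 2.05 times as frequent. Among the next hexamers, singled out after their values were seen, were CTTATC and TGATAA, which contain the GATA sequence bound by GATA factors. CTTATC was at 16.9% of summits and 4.41% of flanks, and TGATAA at 24.0% and 10.1%. CGTCTC (13.8% and 2.66%) and ACGCAG (11.3% and 1.86%) had ratios of 5.21 and 6.10 to the flanks, and of 2.25 and 2.97 to shuffled windows. The ratios to shuffled windows were 4.1 for CTTATC and 3.96 for TGATAA.

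HLH-11 peaks stood at the starts of 4247 of 19973 protein-coding genes (21.3%), called bound genes here, with a summit in the promoter window of any annotated start. Among lists of lipid and energy metabolism, lipid regulators, fat synthesis, mitochondrial fat oxidation and fat lipases were bound more often than other genes, and peroxisomal fat oxidation and insulin and TOR genes passed under some alternatives only. In this and the following groups, each list was tested against all other protein-coding genes with Fisher's exact test, two-sided, and adjusted over 31 lists. The test takes genes as independent, although 1 peak can count for more than 1 member of a list, so its p-values may be too small. Differences in peak density between and along chromosomes were not adjusted for. A second comparison was limited to the 6913 genes with any of the strongest 20000 pooled summits in the window, called the pooled-summit background, where 61.4% of genes were bound. Every bound gene belongs to it by construction and only unbound genes are left out, so it sets genes with a thresholded summit against genes with weaker summits alone. Of 17 regulators of lipid metabolism and nutrient response 16 were bound (94.1%, interval 71.3 to 99.9, adjusted exact p = 1.8e-09). Their strongest peaks were at crh-1, the CREB homologue (signal 884), the nuclear receptors nhr-66 (853) and nhr-49 (634), and hlh-30, the TFEB homologue (755). mdt-15, a Mediator subunit, was the unbound one. Fat synthesis and desaturation genes were bound at 14 of 22, led by the desaturases fat-4 (765) and fat-3 (621), dgat-2 (498) and acl-6 (463), with an adjusted p of 5e-05. Mitochondrial fat oxidation genes followed at 15 of 31 (adjusted exact p = 0.00131), among them acs-2 (605), acdh-9 (496), cpt-2 (413) and cpt-4 (384). Fat lipases were bound at 7 of 15, among them lipl-2 (370), lipl-5 (285), abhd-5.2 (278) and atgl-1 (215). Their adjusted p was 0.0386, and it was 0.266 without replicate 1 and 0.147 with the strongest 3931 peaks. Peroxisomal fat oxidation genes (7 of 16, with acox-1.1, dhs-28, daf-22 and ech-9) and insulin and TOR genes (6 of 17, with rheb-1, akt-2, daf-16 and ragc-1) had adjusted p of 0.0784 and 0.284. The peroxisomal list passed without replicate 1 (adjusted exact p = 0.0454), without replicate 2 (0.0181), with each peak given to the nearest gene (0.0251) and with tRNA, snoRNA and snRNA peaks left out (0.0465), and the insulin and TOR list passed with promoters of 2000 bp (odds ratio 3.92, adjusted exact p = 0.0081). The odds ratio of lipid regulators was 59.5, and 26.8 without replicate 2 and 13.1 with the strongest 3931 peaks. In the pooled-summit background the regulators passed, while the odds ratio went from 6.50 to 2.20 for fat synthesis (adjusted exact p = 0.348), from 3.48 to 1.18 for mitochondrial fat oxidation (adjusted p = 0.859) and from 3.24 to 1.47 for lipases (adjusted p = 0.83).

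Ribosomal protein, autophagy, glycolysis, respiratory chain, chaperone and proteasome genes were bound more often than other genes. Ribosomal protein genes had peaks at 65 of 82 starts (79.3%, interval 68.9 to 87.4, adjusted exact p = 6.56e-28), with rpl-3 (2804), rpl-15 (1679), rpl-20 (1657) and rpl-35 (1502) highest. Their odds ratio was 14.4 with a peak counted for every gene whose window held it, and 3.47 with each peak given to the nearest gene alone (adjusted exact p = 9.56e-07). Autophagy and lysosome genes were bound at 28 of 44 (adjusted exact p = 9.37e-09). The LC3 homologues lgg-2 (1906) and lgg-1 (1092) led them, before atg-18 (890) and the proton pump subunit gene vha-12 (784). Glycolysis and gluconeogenesis genes were bound at 15 of 22 (adjusted exact p = 1.01e-05), including pck-2 (752), pyk-1 (506), pyk-2 (372) and hxk-3 (366). Their odds ratio was 7.96, and 4.29 without replicate 2 and 4.06 with the strongest 3931 peaks. The respiratory chain list was bound at 22 of 44 (adjusted exact p = 5.1e-05), with cox-5A, cox-5B, atp-1 and sdha-1 at the top. Chaperone genes were bound at 26 of 55 (adjusted exact p = 4.91e-05), led by F44E5.4 and F44E5.5, which share 1 peak of signal 2152, then hsp-3 (1292) and dnj-14 (1017). Proteasome genes were bound at 16 of 33 (adjusted exact p = 0.000914), with rpn-3, rpn-11, pbs-1 and rpn-6.1, but not with the strongest 3931 peaks alone (adjusted p = 0.0836). Histone genes did not pass the test (16 of 72, adjusted exact p = 0.885), although his-37 had a signal of 1523. The peaks next highest among histones each served a pair of genes, his-61 with his-62 and his-67 with his-68. In the pooled-summit background ribosomal proteins passed, and the odds ratios of the other lists called here were 2.94 for autophagy and lysosome (adjusted exact p = 0.0555), 3.15 for glycolysis (0.223), 1.98 for the respiratory chain (0.293), 2.05 for chaperones (0.221) and 1.26 for the proteasome (0.779).

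Tissue lists differed widely. Intestine markers were bound at 19 of 22 starts (86.4%, interval 65.1 to 97.1, adjusted exact p = 1.32e-09). They included elt-2, the main intestinal GATA factor (signal 567), the peptide transporter pept-1 (542), the protease cpr-1 (458) and the actin act-5 (442). Muscle markers were bound at 18 of 29 (adjusted exact p = 8.83e-06), with mlc-2, mup-2, tnt-2 and unc-22 at signals of 282 to 309. Heterochronic genes, which time development, were bound at 12 of 16 (adjusted exact p = 2e-05), led by nhl-2 (2232, a peak shared with tag-340), ain-1 (1595), lin-28 (851) and lin-66 (761). Pan-neuronal markers were bound at 10 of 25, with syd-2, snb-1, unc-11 and ric-7. Their adjusted p of 0.0421 was 0.836 without replicate 2, 0.599 with the strongest 3931 peaks and 0.107 with tRNA, snoRNA and snRNA peaks left out. With the strongest 3931 peaks the odds ratio fell from 23.6 to 4.93 for intestine markers and from 6.08 to 3.20 for muscle markers, and with promoters of 500 bp that of heterochronic genes fell from 11.1 to 3.75, all still past the threshold. Over all alternatives the odds ratio of heterochronic genes ranged from 2.52 to 41.2. Skin markers (11 of 29, adjusted exact p = 0.0545) included ajm-1, rnt-1, wrt-1 and sqt-3. They passed without replicate 1 (odds ratio 2.70, adjusted exact p = 0.0164) and with tRNA, snoRNA and snRNA peaks left out (adjusted p = 0.0495), and had an odds ratio of 0.253 with the strongest 3931 peaks (adjusted exact p = 0.324). Vulva and gonad genes (3 of 24, adjusted exact p = 0.52) included let-23, egl-17 and unc-40. Germline markers were bound at 3 of 34, nos-3, gld-2 and spn-4, with an adjusted p of 0.119, and were bound less often than other genes with promoters of 2000 bp (odds ratio 0.265, adjusted exact p = 0.0258). Of 6 vitellogenins 2 had weak peaks, vit-6 (164) and vit-2 (143), with an adjusted p of 0.656. Intestine markers passed in the pooled-summit background, and muscle markers, heterochronic genes and pan-neuronal markers did not (odds ratios 2.83, 2.52 and 1.26, adjusted exact p = 0.178, 0.304 and 0.849).

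Among regulators, nuclear hormone receptor genes were bound at 78 of 274 (28.5%, interval 23.2 to 34.2, adjusted exact p = 0.00753), with nhr-68 (1600), nhr-35 (1009), nhr-66 (853) and nhr-58 (824) highest. The list of bHLH genes did not pass the test, with 10 of 41 bound (adjusted exact p = 0.633), with mdl-1 (1023), hlh-30, mml-1 (308) and aha-1 (286), and mdl-1 and mml-1 belong to the Myc and Max network. Homeobox genes were bound at 16 of 98 (adjusted exact p = 0.317), led by ceh-38 (798), ceh-99, ceh-20 and ceh-60, and were bound less often than other genes with promoters of 500 bp (odds ratio 0.426, adjusted exact p = 0.0235). Xenobiotic enzyme genes were bound at 61 of 190 (adjusted exact p = 0.000914), with gst-42, ugt-20, ugt-49 and cyp-13A2, but not in the pooled-summit background (odds ratio 1.6, adjusted p = 0.178).

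Chemoreceptor, neuropeptide, F-box, C-type lectin and major sperm protein genes were bound less often than all other genes. Chemoreceptor genes, used in sensory neurons, had peaks at 29 of 1316 starts (2.20%, interval 1.48 to 3.15, adjusted exact p = 5.89e-97), with srh-2 (1570), srh-282, srv-1 and srh-70 highest. Neuropeptide genes were bound at 9 of 147 (6.12%, adjusted exact p = 3.25e-06), among them ins-39 (793), nlp-40 and, at 1 shared peak, nlp-31 and nlp-34. F-box genes were bound at 31 of 322 (adjusted exact p = 1.53e-07), with fbxa-83, fbxc-19, fbxb-85 and fbxc-29, and C-type lectin genes at 31 of 240 (adjusted p = 0.00186), with clec-126, clec-150, clec-78 and clec-178. No major sperm protein gene was bound of 48, which leaves an upper limit of 7.40% (adjusted exact p = 5e-05). Collagens were bound at 35 of 177 (adjusted exact p = 0.736), including col-63, col-38, bli-6 and col-85, but were bound less often than other genes with the strongest 3931 peaks (odds ratio 0.334 against 0.912, adjusted exact p = 0.00213). The pooled-summit background, which leaves out unbound genes alone, holds 54 of the 1316 chemoreceptor genes. Of these the 29 were bound, an odds ratio of 0.726 against 0.0771 among all genes (adjusted exact p = 0.37), so few chemoreceptor genes had a pooled summit of either kind. F-box genes (0.693, adjusted exact p = 0.304), C-type lectins (0.669, adjusted p = 0.293) and major sperm proteins (0 of 3, adjusted exact p = 0.178) did not pass there either.

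In all, 16 lists were bound more often and 5 less often than other genes, and these counts depended on the background. In the pooled-summit background 6 lists passed the test. Ribosomal proteins (odds ratio 6.89, adjusted exact p = 3.44e-07), lipid regulators (10.1, adjusted p = 0.0357), intestine markers (5.99, adjusted p = 0.0357) and nuclear hormone receptors (2.06, adjusted p = 0.0146) were bound more often there. Neuropeptides (0.331, adjusted exact p = 0.0386) and collagens (0.444, adjusted p = 0.0041) were bound less often, and 5 of the 6 lists were among those that passed against all genes. Of the 21 lists called against all genes, 20 had an odds ratio nearer 1 in the pooled-summit background, among them all 16 that lost their call.

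**Figure D4:**
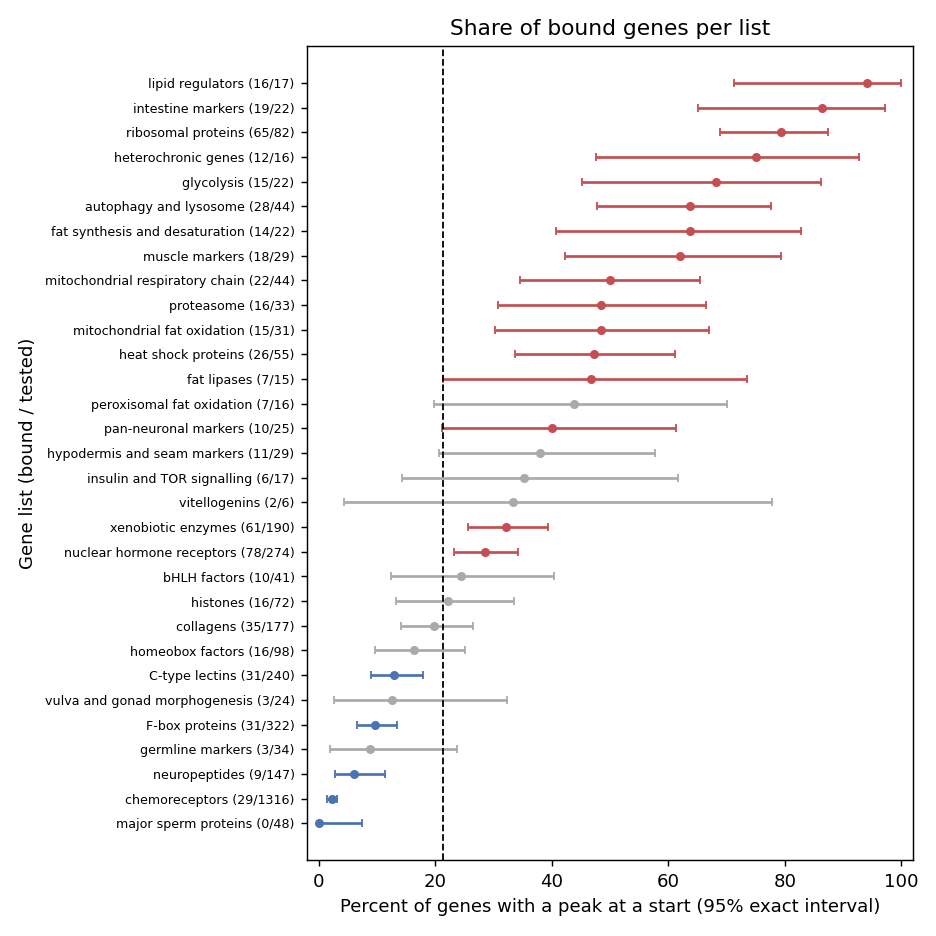
Percent of each gene list with a peak at a start (horizontal axis, with 95% exact binomial intervals) for the 31 lists (vertical axis, bound and tested members in brackets); red lists were bound more often and blue lists less often than other genes at an adjusted p under 0.05, and grey lists did not pass. The dashed line is the 21.3% of all protein-coding genes that were bound, with lipid regulators highest at 94.1%.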

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

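The directions of the X excess, the promoter excess, the CAGCTG excess, its rise with peak strength and the rank agreement of the replicates held under every alternative run, each still past its threshold. Leaving out tRNA, snoRNA and snRNA peaks, equal start positions, and every alternative for the hexamer count and for hexamers other than CAGCTG were chosen after seeing the data. Their sizes moved in places. The CAGCTG share of the strongest 1965 peaks less that of the weakest 1965 was 4.02 percentage points. It was 2.29 points between the strongest 3931 and the weakest 3931, and 7.23 points when the same measure was taken within the strongest 3931 alone. Bound genes numbered 2467 with the strongest 3931 peaks, by construction fewer peaks, 3436 with promoters of 500 bp, 5337 with promoters of 2000 bp and 3700 with the nearest gene only. Replicate support in both replicates was 69.6% within 50 bp, 81.9% within 200 bp, 83.2% for an overlap of 1 bp, 67.7% for a reciprocal overlap of 50%, and 94.6% and 41.6% with longer and shorter replicate lists, which follows from how much each setting accepts. The number of lists past the threshold was 21, and 6 among genes with one of the strongest 20000 pooled summits. That background leaves out unbound genes alone, so by its construction fewer members were tested and genes with no summit no longer count. The odds ratios were nearer 1 for 20 of the 21 called lists and for all 16 that lost their call, and how much of the loss comes from size and how much from the odds ratios was not tested. Against all genes it ranged from 19 to 23. Of 310 values of single lists under the alternatives, 270 kept both their direction and their side of the threshold, 22 lost their call (16 of these in the pooled-summit background), 11 gained one and 7 changed direction. None of those 7 passed the test in either direction, and the cause was not tested. Their odds ratios were 0.253 for skin markers, 1.01 for vulva and gonad genes and 0.546 for vitellogenins (0 bound, 0.5 added to each cell) in the strongest 3931 peaks, 0.767 for skin markers and 0.628 for vitellogenins in the pooled-summit background, and 0.983 and 0.709 for histones with 2000 bp upstream and with the nearest gene only. Among the 24 named hexamers, those that changed direction against shuffled windows, counted as the ratio to the shuffled share, were AAAATT (1.01), AAAAAT (1.3), TAAAAA (1.15) and AAAATA (1.46), and against pooled summits below the threshold CACCTG (0.958), CAGATG (0.926), CAAATG (0.953) and CATATG (0.839). Of these, AAAAAT, TAAAAA and AAAATA passed the test in the new direction. The size of a replicate-only list is fixed by construction, so the peak count has no such value. Unknown depth limits what the absence of a peak can mean.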

Other observations

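The tests of sequence at the peaks of gene lists and of non-coding gene classes, of CAGCTG by strength against other E-boxes and of X below the threshold were chosen after related results were seen. The bound for the CAGCTG strength test was revised once its values were known: at first any E-box with a larger odds ratio was to count against CAGCTG, and then only one larger beyond the spread. HLH-11 peaks were frequent at genes of some non-coding RNA classes and rare at others. Of 612 tRNA genes, 264 (43.1%) had a summit within 200 bp, 10.8 times the share when peaks were shifted along their chromosomes. The share was 30.3% of snoRNA genes (7.58-fold), 24.0% of snRNA genes (6.58-fold), 25.8% of lincRNA genes (2.37-fold) and 9.58% of microRNA genes (2.40-fold). Pseudogenes (2.16%, 0.193-fold) and piRNA genes (0.462%, 0.18-fold) had fewer peaks than shifted ones gave. These 7 classes reached an adjusted p of 0.00114 over 8 classes, with the smallest p that 1000 shifts can give (permutation p = 0.001), and none of the 20 rRNA genes had a peak (adjusted p = 0.532).

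The sequence at the peaks differed between groups of bound genes. TGATAA, a GATA-type sequence, lay within 50 bp of the summit at the strongest peak of 13 of 19 bound intestine markers (68.4%, interval 43.4 to 87.4) against 21.2% of other bound genes (Fisher's exact p = 1.39e-05). Bound F-box genes had it at 17 of 31 (54.8%) and bound C-type lectin genes at 15 of 31 (48.4%), while bound ribosomal protein genes had it at 2 of 65 (3.08%). These 4 were the tests past the threshold among 69 (3 hexamers over the lists with at least 10 bound members), with adjusted p of 0.000959, 0.00105, 0.0226 and 0.00105. TGATAA was at 22.5% of the strongest and 21.5% of the weakest 1965 peaks (Fisher's exact p = 0.464), whereas ACGCAG was at 17.7% and 7.33% (odds ratio 2.71, p = 5.47e-23). CTTATC, the other GATA-type hexamer named, was at 16.9% and 13.7% (odds ratio 1.28, Fisher's exact p = 0.00597). A candidate explanation, as a hypothesis, is that part of the list comes from promoters active in the intestine, where GATA factors act. The 68.4% at intestine markers goes with this for 1 list, but the shares at F-box and C-type lectin genes were also high. How often promoters of intestine markers hold TGATAA away from summits was not measured. The 68.4% therefore cannot tell this explanation from the usual sequence of those promoters, and no tissue was assayed separately.

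Peaks at tRNA and ribosomal protein genes are the first pattern. Weak background enrichment, alike at strong and weak peaks, is argued against for ribosomal protein genes. Among genes with one of the strongest 20000 pooled summits in the window, they had a thresholded summit more often than the others (65 of 71, odds ratio 6.89). Thresholded summits lay within 200 bp of a tRNA gene more often than pooled summits over 500 bp from any thresholded summit (odds ratio 6.20, Fisher's exact p = 4.67e-61). This argues against an equal share at such distant summits alone, of which 0.516% lay near a tRNA gene. Leaving out the nearer pooled summits may raise the odds ratio, and by how much was not tested. Binding through CAGCTG is argued against for tRNA genes, where 0.816% of 245 peaks had that sequence against 4.44% of the other peaks (Fisher's exact p = 0.00218). For ribosomal protein genes, 5 of 65 (7.69%) had it at the strongest peak against 4.57% of other bound genes (exact p = 0.225). The rule set beforehand counted only a lower share against such binding, so this test cannot tell. As the whole cause, such binding is argued against by a point outside that rule: most of these peaks lacked CAGCTG within 50 bp of the summit. That point applies equally to the full list, where 4.32% of summits had CAGCTG. For the 5 genes that had it, such binding stays open. Strong recovery of open, highly transcribed chromatin with any antibody, and reads shared among tRNA copies, were not tested, and no biological explanation was tested against them.

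CAGCTG at summits is the second pattern. Base composition as its whole cause is argued against by windows shuffled with their dinucleotide counts kept, where the real share was 2.56 times the shuffled one (exact sign test p = 1.27e-22). An equal share at thresholded summits and at pooled summits below the threshold is argued against by a ratio of 1.26 (Fisher's exact p = 0.000484). Those below the threshold had it in 3.44% of cases, against 1.67% in the flanks of thresholded peaks. The 2 sets of summits were not matched: 53.0% and 32.1% lay in promoters, and AAAATT was at 15.6% and 24.1%. Whether the ratio goes with such differences was not tested, so it cannot tell binding from a general property of enriched regions. Direct binding to CAGCTG may explain the odds ratio of 2.37 between the strongest and weakest peaks. CACGTG, however, had 2.60, which the first bound would have counted against CAGCTG. Among named hexamers that are not E-boxes, ACGCAG had 2.71 and CGTCTC 2.47, while TGATAA had 1.06 and AAAATT 0.504. This test therefore cannot tell CAGCTG from an E-box of other bHLH factors, or from other sequences that rise with peak strength.

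Peak density on X is the third pattern. More enriched regions of any strength on X is argued against as the whole cause by the ratio of 1.15 among pooled peaks below the threshold, against 1.45 (Fisher's exact p = 2.4e-13). More CAGCTG on X is argued against by an X to autosome ratio of 0.916 for that sequence (interval 0.882 to 0.951), and more gene starts on X by a ratio of 0.761 (0.736 to 0.786). A preference for genes used outside the germ line, which are common on X, remains possible and was not tested here.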
